A study of Drosophila melanogaster with 24 samples.

How the data were processed

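The series compared flies in which lysine 9 of histone H3 was replaced by arginine (K9R) in canonical H3, in the replacement variant H3.3, or in both. RNA was sequenced from whole larvae of the first instar in 4 genotypes, and open chromatin was measured in imaginal wing discs of wandering larvae of the third instar in another 4 genotypes, with 3 libraries per genotype. Per the labels, RNA libraries were made with the NuGEN Ovation kit for model organisms, and the discs' libraries with the Rubicon ThruPLEX kit. Open chromatin was measured by FAIRE, which recovers DNA fragments that formaldehyde did not link to nucleosomes. Groups were read from the labels, and every library had one.

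The submitters' processing notes name Bowtie2 2.3.2, TopHat2 2.1.1, Cufflinks 2.1.1, SAMtools 1.5, bedtools 2.2.25.0, MACS2 and DESeq2 with genome build dm6, without saying which step used which tool. Versions of MACS2 and DESeq2, the counting step, the treatment of reads that map to several places, and the gene annotation behind the RNA loci are not given in the sources used here. The values analysed were 3 RNA tables of 10253 loci and 4 FAIRE tables of 19738 regions, each the authors' own DESeq2 comparison of one genotype over another. Per the file headers, each holds a mean over all libraries of the assay of counts divided by size factors, a signal never below 0. Per the file headers, each also holds the log2 fold change, its standard error on the log2 scale, and the Wald statistic, a score equal to the fold change over that error. The p-value and the Benjamini-Hochberg adjusted p-value are as deposited by the authors. No column held values of a single library. Depth per library, the spread between single libraries and any pairing of them therefore stay unknown, and the only errors printed are the authors' deposited standard errors.

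The authors' deposited standard errors had an upper limit, 0.306 for RNA and 0.267 for FAIRE, and 850 RNA loci with a mean count under 1 had a standard error under 0.1. Such a limit arises when fold changes are shrunk towards 0, so the fold changes of loci with few counts may be understated. Adjusted p-values were present for 8123 loci in the canonical K9R table and 7634 in each of the other RNA tables, and for 19733 regions in each FAIRE table. A missing adjusted p-value was kept as missing, and the locus was left out of counts of calls.

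The RNA tables give coordinates without gene names. Names were taken from the Release 6 RefSeq gene table, the same assembly as dm6, when a gene and a locus shared at least 50% of their joint span. This named 9567 loci, of which 6172 matched a gene at both ends, and left 686 unnamed, 201 of them on scaffolds, the Y or the mitochondrial genome. Another limit is that 3340 loci hold 2 or more genes, whose reads the tables do not separate. Strand was not used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. FAIRE regions were assigned to the gene they overlap or, failing that, the nearest one at any distance. Positions are 1-based.

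Calls are those of the authors' Wald test with an adjusted p-value under 0.05. The genome was divided into pericentromeric sequence (2L from 22 Mb, 2R to 5.4 Mb, 3L from 23 Mb, 3R to 4.6 Mb, X from 23 Mb), chromosome 4, the Y, unplaced scaffolds and the remaining arms. Shares of called loci or regions in each class were compared with the rest of the genome by a two-sided Fisher exact test with Benjamini-Hochberg adjustment. This test, used by arm as well, counts each locus or region as independent. Where neighbours change together, its p-values overstate the evidence. Of the 26 gene lists fixed, the transposable element families matched none of their 46 names and the targeted histone genes had only 1 measured locus. The others were tested with cameraPR of limma 3.58.1 on the Wald statistic, two-sided, with a preset correlation of 0.01 and adjustment over all lists and comparisons. The text gives the measured loci of a list, and the test left out those without a p-value, so that it held 19 of 23 fat body, 20 of 23 muscle, 5 of 6 Y, 33 of 34 replication, 87 of 88 cuticle and 31 of 32 immune loci. An estimated correlation needs values per library and could not be computed, so a preset of 0.05 stands in for it as an alternative. Differences between comparisons were tested per locus as the difference of log2 fold changes over the root of the summed squared standard errors, two-sided, with Benjamini-Hochberg adjustment. Where the comparisons share control libraries, this error is too large and the test misses real differences. An alternative error removed the shared control, taken to hold 50% of the smaller squared standard error. In FAIRE, where the tables allow it to be computed, that share had a median of 52.5%. Overlaps of calls were set beside the overlap of independent lists, and correlations, covariances and shares of equal sign beside their means in 100 simulations of unchanged groups sharing one control. RNA fold changes of loci overlapped by FAIRE regions were compared by permutation, 100000 resamples, two-sided. The planned use of transcription starts was replaced by overlap, because the gene table used here gives no strand.

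The gene lists, location boundaries, tests and the rule for named genes were fixed before the data were examined. Under that rule the text names the targeted genes and, per RNA comparison, the 8 loci with the highest and the 8 with the lowest Wald statistic. These were taken among calls with an absolute log2 fold change of 1 or more, or of any size where fewer than 8 passed. For each difference test it names the 5 with the largest statistics on each side, a statistic being the difference over its error. Of the members picked per list and comparison (up to 4 with the smallest adjusted p-value) and of the 5 highest and 5 lowest FAIRE regions per comparison only a part is named, which departs from the rule. Some loci picked in one comparison are also given in others. Unnamed loci are counted only. Splits by chromosome arm, the 5 blocks of FAIRE regions, the histone classes and roX2 were chosen after values had been seen.

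Alternatives were an adjusted p-value under 0.01, an absolute log2 fold change of 1 or more, adjustment over every locus with a p-value, a mean count of at least 10, boundaries moved by 1 Mb either way, other statistics and presets for the list test, and the error with the shared control removed. The difference test was tested on simulated data made from the deposited standard errors, with 200 changed features among 10072 loci or 19733 regions. For combined K9R against canonical K9R it recovered 12.0% of changes of 0.5 on the log2 scale, 65.5% of changes of 1 and all of 2, calling 0 unchanged loci at each size. For combined K9R against H3.3 K9R it recovered 7.5%, 65.0% and 100%, and for the FAIRE interaction 5.5%, 74.0% and 100%, where 1, 5 and 8 unchanged regions were called. The list test, tested on simulated data with the midgut list moved by 1 unit of the statistic, called it in 100 of 100 draws and 2.39% of the other lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.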

Results

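The series held 24 libraries, 12 per assay, from 4 genotypes per assay with 3 libraries each. Its title asks whether lysine 9 of canonical histone H3 and of the replacement variant H3.3 can stand in for each other. Both were changed to arginine (K9R), alone and together. RNA was measured in whole larvae of the first instar that lacked their own canonical histone genes and lived on a transgenic array of 12 copies. The control array was wild type. Canonical K9R larvae carried the array with K9R. H3.3 K9R larvae carried the wild-type array, no H3.3A and an H3.3B gene with K9R, and combined K9R larvae carried the H3.3 changes with the K9R array. Open chromatin was measured by FAIRE in wing discs of the third instar from wild type (yw), H3.3A null, H3.3B-K9R and the double mutant, all with their own canonical histone genes. Depth per library is unknown. The median mean normalized count was 108 per RNA locus and 85.9 per FAIRE region. The top 10 RNA loci held 53.9% of the summed mean counts. All 29 loci with a mean count over 100000 lay on scaffolds or in pericentromeric sequence. Without them the sum of mean counts fell from 2.29e+07 to 7.43e+06. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples. Positions are on dm6, and every fold change is a log2 value over the control with the authors' standard error after the ± sign.

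The targeted genes came first. His3.3A (2L) lies in a locus at 5055058 to 5058248 that also spans Nepl3, whose reads the tables do not separate. In the authors' deposited table this locus stood at −0.34 ± 0.21 in canonical K9R, −0.55 ± 0.21 in H3.3 K9R (adjusted p = 0.132) and −0.82 ± 0.21 in combined K9R (adjusted p = 8.4e-04). His3.3B (X, 9152523 to 9156669), which carries a codon change and no deletion, stood at 0.02 ± 0.09, 0.27 ± 0.09 (adjusted p = 0.0432) and 0.13 ± 0.09 in the same order in the authors' deposited table. The RNA level of His3.3B does not test its genotype. In wing discs, the FAIRE region at His3.3A (2L, 5055001 to 5055291) fell in the H3.3A null, −1.31 ± 0.19 (adjusted p = 2.7e-10), and in the double mutant, −1.66 ± 0.20 (adjusted p = 2.1e-15), per the authors' deposited table. There it stood at 0.23 ± 0.17 in H3.3B-K9R (adjusted p = 0.754 in the authors' deposited table), which keeps H3.3A.

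Larvae whose canonical H3 carried K9R had more RNA from pericentromeric, Y and unplaced sequence, and lower values at the reference copies of the H3 genes. The authors' deposited table called 288 of 8123 tested loci (3.55%), 247 higher and 41 lower. Of the higher loci 178 had no gene name. Marf1, an RNA-binding protein of oogenesis (2L, 22308666 to 22368796), rose by 2.27 ± 0.19 (adjusted p = 3.4e-29), and DIP-lambda, a cell-surface protein of the immunoglobulin family (2R, 326779 to 718433), by 1.45 ± 0.13 (adjusted p = 1.5e-25) in the authors' deposited table. Also higher there were lncRNA:CR42646 (2R, 5363253 to 5367357), 1.93 ± 0.27, CG43291 (3R, 14236534 to 14244677), 1.86 ± 0.19, and tut, a partner of bam in the male germline, 1.55 ± 0.30, all in the authors' deposited table. Su(Ste):CR42407, a Y repeat of the family whose small RNAs silence Stellate, rose by 1.22 ± 0.26, CG13947 by 1.09 ± 0.24 and Maf1, a repressor of RNA polymerase III (2R, 1512473 to 1527095), by 1.06 ± 0.17 in the authors' deposited table. ImpE2, an ecdysone-inducible gene, decreased by 1.85 ± 0.31, the serpin Spn100A by 1.53 ± 0.28, the chitinase Cht10 by 1.15 ± 0.20 and the small heat shock gene Hsp27 by 1.04 ± 0.29 (adjusted p = 0.0133) in the authors' deposited table. Lower too were mas, −1.37 ± 0.29 (adjusted p = 2.1e-04), nw, −1.15 ± 0.30, neo, −1.06 ± 0.29, CG40160, −0.82 ± 0.15, and the poly(ADP-ribose) polymerase gene Parp1 (3R, 3461351 to 3587054), −0.85 ± 0.18, per the authors' deposited table. Some of these loci span a further gene, Marf1 for instance lncRNA CR43359, and their reads cannot be told apart.

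Of the loci tested in canonical K9R, 25.0% of the pericentromeric ones (89 of 356), 29.1% of those on the Y (16 of 55) and 48.4% of those on scaffolds (78 of 161) were higher, against 0.829% on the arms (62 of 7482). By Fisher exact test each class was enriched over the rest of the genome, with odds ratios of 16.0 (adjusted p = 1.8e-59), 13.9 (adjusted p = 1.1e-11) and 43.3 (adjusted p = 2.4e-77). Chromosome 4, which is also rich in H3K9 methylation, had 2 of 67 loci higher (odds ratio 0.981, adjusted p = 1). Pericentromeric loci were also enriched among the lower ones (9 of 356, odds ratio 6.27, adjusted p = 1.1e-04). With an absolute log2 fold change of 1 or more these were 2 of 356 (adjusted p = 0.113). With boundaries 1 Mb towards the centromere the pericentromeric odds ratios were 26.5 for higher and 7.87 for lower loci, and into the arms 7.81 and 17.5. That move makes the histone array of the reference genome on 2L pericentromeric, and 15 of the 25 lower loci there were its His3 copies. These larvae lacked their own canonical histone genes, so reads placed at that array do not measure a locus present on 2L. With the array left out, chosen after seeing the data, the ratio for lower loci was 11.7 with the fixed boundaries and 8.05 into the arms (10 of 586, Fisher exact test, p = 7.3e-06). Where Y loci were higher, lncRNA:roX2, a dosage compensation RNA made in males, stood at −0.15 ± 0.24 in canonical K9R, −0.06 ± 0.24 in H3.3 K9R and −0.23 ± 0.24 in combined K9R in the authors' deposited table, beside medians of 0.75, 0.57 and 0.52 over 45 Y loci. roX2 was looked up after values had been seen. Scaffolds and the Y hold much repeated sequence. In canonical K9R 13 of 159 named pericentromeric loci were higher, so most of the 89 higher ones had no name. How reads with several positions were counted is not given.

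The canonical histone list was lower in canonical K9R (103 loci, median −0.28, adjusted p = 2.2e-08 by cameraPR), with 0 higher and 15 lower, and 15 lower when adjusted over the list alone. All 15 lower loci were copies of His3, with a median of −0.82 in the authors' deposited table, among them His3:CG33830 (2L, 21479636 to 21480164) at −1.01 ± 0.24 (adjusted p = 0.00103) and His3:CG33827 at −0.97 ± 0.24. Medians of the other classes in the authors' deposited table were 0.21 for His1, −0.35 for His2A, −0.28 for His2B and −0.25 for His4, with 0 loci called. Copies within a class are nearly identical, so values of single copies are uncertain. The list test counts 103 copies of 5 genes as separate loci, so its p-values here and in combined K9R overstate the evidence. Whether the K9R codons of the transgenic array altered the assignment of reads to the reference copies was not analysed here. Heat shock genes fell (18 loci, median −0.39, adjusted p = 7.5e-05), with 0 higher and Hsp27 lower, also when adjusted over the list alone. That list holds near-identical Hsp70 copies counted as separate loci, so its p-values in each genotype may overstate the evidence. The pericentromeric gene list rose (24 loci, median 0.12, adjusted p = 1.2e-04), with 6 higher and 1 lower, and 9 and 2 adjusted over the list alone. Its higher members included the SNARE gene Snap25, 0.62 ± 0.12 (adjusted p = 1.2e-05), the ionotropic receptor Ir40a, 0.60 ± 0.14 (adjusted p = 6.9e-04), and nvd, of the first step of ecdysone synthesis, 0.49 ± 0.11, in the authors' deposited table. On ranks the list's adjusted p was 0.0598. DNA replication genes (34 loci, median −0.24, adjusted p = 0.0130), oxidative stress genes (35 loci, median −0.15, adjusted p = 0.0390) and ribosomal protein genes (62 loci, median −0.07, adjusted p = 0.0102) fell as lists. Only RpLP2 among their members was called, at −0.45 ± 0.11 (adjusted p = 0.00141) in the authors' deposited table, and adjusted over the list alone the counts were the same. At an unadjusted p under 0.05, 1 replication gene was higher and 2 lower, and 3 oxidative stress genes were lower. With a preset correlation of 0.05 the 3 lists' adjusted p-values were 0.180, 0.265 and 0.214, that of oxidative stress genes was 0.0568 among loci with a mean count of at least 10, and that of ribosomal proteins 0.325 on fold changes.

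**Figure D1:**
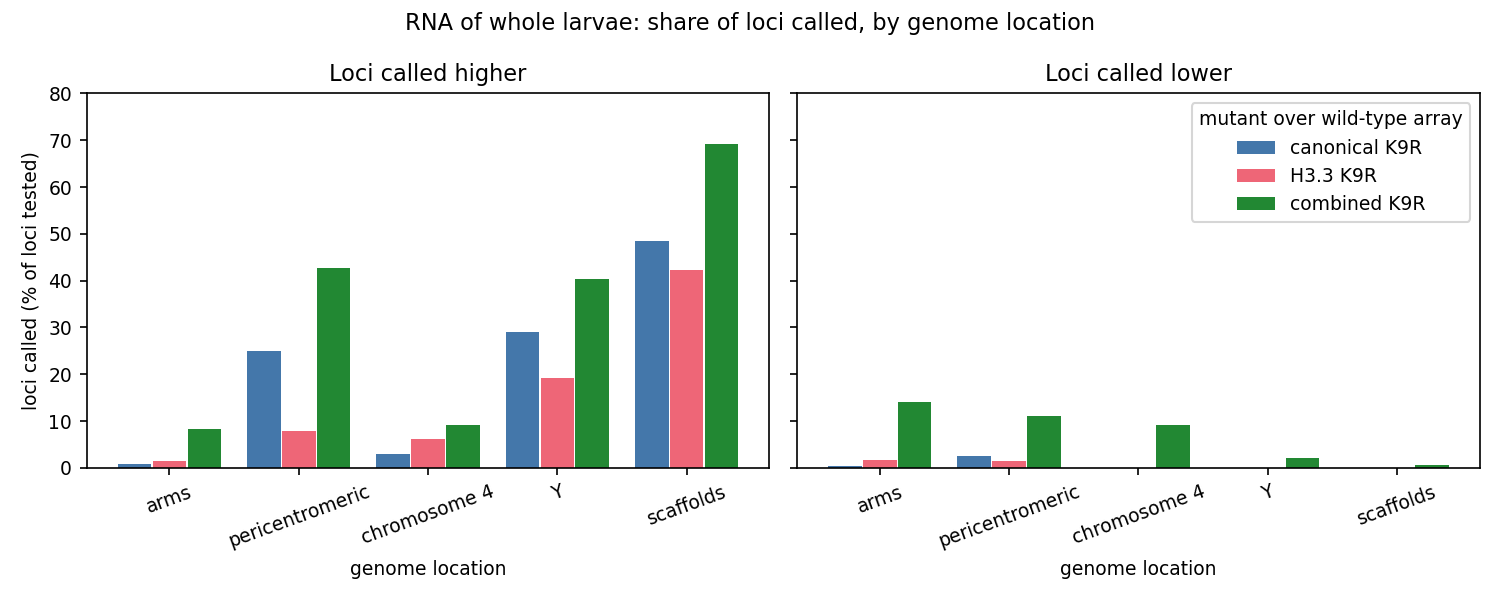
Percent of tested RNA loci called higher or lower per location class in each K9R genotype, from the authors' deposited adjusted p-values under 0.05. Scaffold, Y and pericentromeric loci had the highest shares called higher, 48.4%, 29.1% and 25.0% in canonical K9R, against 0.829% of arm loci.

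H3.3 K9R larvae, with a wild-type canonical array, had more RNA from scaffold, Y and some pericentromeric loci, and strong changes of single genes on the X and 2L. The authors' deposited table called 329 of 7634 tested loci (4.31%), 203 higher and 126 lower. Of the higher loci 103 had no name. CG44774 (X, 4921678 to 4938105) rose by 2.05 ± 0.15 (adjusted p = 1.2e-36), Neto, an auxiliary subunit of glutamate receptors (X, 13445884 to 13527282), by 1.20 ± 0.11 (adjusted p = 2.3e-25), and the ubiquitin ligase gene hiw (X, 15010137 to 15063429) by 1.09 ± 0.13 (adjusted p = 6.7e-14) in the authors' deposited table. Higher there as well were the receptor gene mthl8, 1.88 ± 0.30, snRNA:U1:82Eb, 1.5 ± 0.26, the cytochrome P450 gene Cyp309a2, 1.09 ± 0.17, and Su(Ste):CR42407, 1.28 ± 0.26, all from the authors' deposited table. lncRNA:CR40469 (X, 122493 to 122706) decreased by 3.00 ± 0.18 (adjusted p = 1.3e-57), the fucosyltransferase gene FucTC (X, 23007672 to 23011401) by 2.16 ± 0.21 (adjusted p = 1.1e-22) and CR11023 at the tip of 2L (7529 to 9484) by 2.64 ± 0.30 in the authors' deposited table. CG43291 was higher too, 1.06 ± 0.19, and CG33337, 1.53 ± 0.29 (adjusted p = 1.7e-05), in the authors' deposited table. On 2L, CG43774 stood at −1.83 ± 0.22, its neighbour CG43773 at −1.75 ± 0.26 and CG2772 at −1.64 ± 0.25, CG43349 at −1.37 ± 0.21, and ImpE2 on 3L at −2.20 ± 0.31 and Spn100A on 3R at −1.40 ± 0.28, all called in the authors' deposited table. The H3.3 mutations themselves lie on the X and 2L. On the arms, 5.06% of X loci were called (57 of 1126) and 3.49% of 2L loci (47 of 1345), against 2.53%, 2.48% and 2.51% on 2R, 3L and 3R, pericentromeres left out. The X share exceeded that of 2R, 3L and 3R (odds ratio 2.07, adjusted p = 7.3e-05), and that of 2L did not pass (odds ratio 1.41, adjusted p = 0.0793). In canonical K9R 28 of 1434 loci on 2L were called (odds ratio 1.88 against 2R, 3L and 3R, adjusted p = 0.0163). Of these, 15 were His3 copies of the reference histone array, which these larvae lacked on 2L. On the X 15 of 1187 were called (odds ratio 1.21, adjusted p = 0.601). With the array left out, chosen after seeing the data, 13 of 1331 loci on 2L were called in canonical K9R (odds ratio 0.93, Fisher exact test, p = 1). In H3.3 K9R these were 47 of 1242 (odds ratio 1.53, Fisher exact test, p = 0.0191). Counted over 2R, 3L and 3R alone, 2.51% of loci were called in H3.3 K9R and 1.05% in canonical K9R, an alternative chosen after seeing the data.

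By location in H3.3 K9R, 42.3% of scaffold loci (66 of 156, odds ratio 39.3, adjusted p = 1.0e-64), 9 of 47 Y loci (odds ratio 9.02, adjusted p = 6.8e-06) and 7.83% of pericentromeric loci (27 of 345, odds ratio 3.43, adjusted p = 9.3e-07) were higher. The pericentromeric ratio was 2.04 with boundaries 1 Mb into the arms. Chromosome 4 had 4 of 65 loci higher (odds ratio 2.43, adjusted p = 0.155). As a list, the genes named on chromosome 4 rose slightly (34 loci, median 0.10, adjusted p = 0.0186), with 1 called, the synaptotagmin gene Syt7 at 0.48 ± 0.15 (adjusted p = 0.0420) in the authors' deposited table, and 0 adjusted over the list alone. The chromosome 4 list's adjusted p was 0.216 on fold changes and 0.189 with a preset correlation of 0.05. Heat shock genes fell (18 loci, median −0.43, adjusted p = 2.2e-07), 5 of them called lower and 8 adjusted over the list alone, with 0 higher. They included Hsp27 at −1.38 ± 0.29 (adjusted p = 1.5e-04) and the near-identical copies Hsp70Ba, Hsp70Bbb and Hsp70Bc at −1.12, −1.12 and −1.13, each ± 0.30, in the authors' deposited table, the copies' values being uncertain one by one. Midgut digestive enzymes fell (28 loci, median −0.24, adjusted p = 2.1e-05), with 0 higher, 6 lower and 7 lower adjusted over the list alone. Among them were the proteases Jon66Ci, −1.35 ± 0.25, Ser6, −0.79 ± 0.17, and Jon99Ciii, −0.56 ± 0.14, in the authors' deposited table. Ribosomal protein genes fell as a list (62 loci, median −0.11, adjusted p = 0.00286) with RpL3 lower, −0.38 ± 0.12, and RpS5b higher, 0.86 ± 0.24, in the authors' deposited table, the same counts adjusted over the list alone. DNA damage genes (23 loci, median −0.17, adjusted p = 0.0292) fell with 0 members called and 6 lower at an unadjusted p under 0.05. Their adjusted p was 0.189 with a preset correlation of 0.05, and that of the ribosomal proteins 0.159, or 0.247 on fold changes. Canonical histone genes had a median of 0.01 (adjusted p = 0.130) with 0 called, and pericentromeric genes 2 higher and 1 lower (adjusted p = 0.155), the same adjusted over the list alone. Immune genes moved both ways, with 2 higher and 3 lower of 32, the same adjusted over the list alone (adjusted p = 0.942). Of these, DptB stood at 1.20 ± 0.30, Drsl2 at 0.93 ± 0.28, the cytokine gene upd3 at −1.25 ± 0.28 and Tep4 at −1.06 ± 0.24 in the authors' deposited table.

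Combined K9R larvae had more called loci than either single genotype, and the shares called higher were largest on scaffolds, at pericentromeres and on the Y. The authors' deposited table called 1905 of 7634 tested loci (25.0%), 869 higher and 1036 lower, 284 of the higher and 38 of the lower without a gene name. CG43291 rose by 3.23 ± 0.18 (adjusted p = 1.5e-66), lncRNA:CR42646 by 3.47 ± 0.26, CG44774 by 2.5 ± 0.15 (adjusted p = 3.5e-56), Marf1 by 2.19 ± 0.19 and Maf1 by 2.08 ± 0.17 in the authors' deposited table. pyd, a junction protein of the ZO family (3R, 8824411 to 8931896), rose by 1.72 ± 0.13 (adjusted p = 1.4e-37), Neto by 1.61 ± 0.11, l(2)41Ab (2R, 1347799 to 1444167) by 1.58 ± 0.12, DIP-lambda by 1.57 ± 0.13 and hiw by 1.25 ± 0.13 in the authors' deposited table. CG31233 (3R, 21749875 to 21753237) fell to −1.5 ± 0.11 (adjusted p = 9.7e-38) and BckdhB, of branched-chain ketoacid breakdown (2R, 1590484 to 1598342), to −1.48 ± 0.14 (adjusted p = 6.2e-25) in the authors' deposited table. CG41099 stood there at −1.74 ± 0.18 and the transporter gene MFS3 at −1.07 ± 0.11, both called in the authors' deposited table. Lower as well were lncRNA:CR40469, −2.65 ± 0.18, FucTC, −1.93 ± 0.21, ImpE2, −2.22 ± 0.30, nw, −2.1 ± 0.30, Parp1, −1.61 ± 0.18, CG40160, −1.42 ± 0.16, and Cht10, −1.59 ± 0.20, per the authors' deposited table. Higher loci made up 42.6% of the pericentromeric ones (147 of 345, odds ratio 6.76, adjusted p = 6.2e-52), 19 of 47 on the Y (odds ratio 5.38, adjusted p = 8.1e-07) and 69.2% on scaffolds (108 of 156, odds ratio 19.9, adjusted p = 4.7e-66), against 8.38% on the arms (588 of 7019). The pericentromeric ratio was 3.2 with boundaries 1 Mb into the arms, 13.7 towards the centromere and 20.1 with an absolute log2 fold change of 1 or more. Lower loci were 14.1% of the arm loci (990 of 7019), more than in the rest of the genome (odds ratio 2.02, adjusted p = 3.3e-06). This ratio was 1.3 with boundaries 1 Mb into the arms (adjusted p = 0.0279), which take 35 lower histone copies out of the arms. With the array left out, chosen after seeing the data, it was 1.82 there. For all loci it was 1.02 with an absolute log2 fold change of 1 or more (163 of 7019, adjusted p = 1). Chromosome 4 had 6 of 65 loci higher (odds ratio 0.791, adjusted p = 0.872). On the X arm 293 of 1126 loci were called (odds ratio 1.26 against 2R, 3L and 3R, adjusted p = 0.00651). With an absolute log2 fold change of 1 or more, 456 loci were called, 279 higher and 177 lower, against 162 in canonical K9R and 130 in H3.3 K9R.

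**Figure D2:**
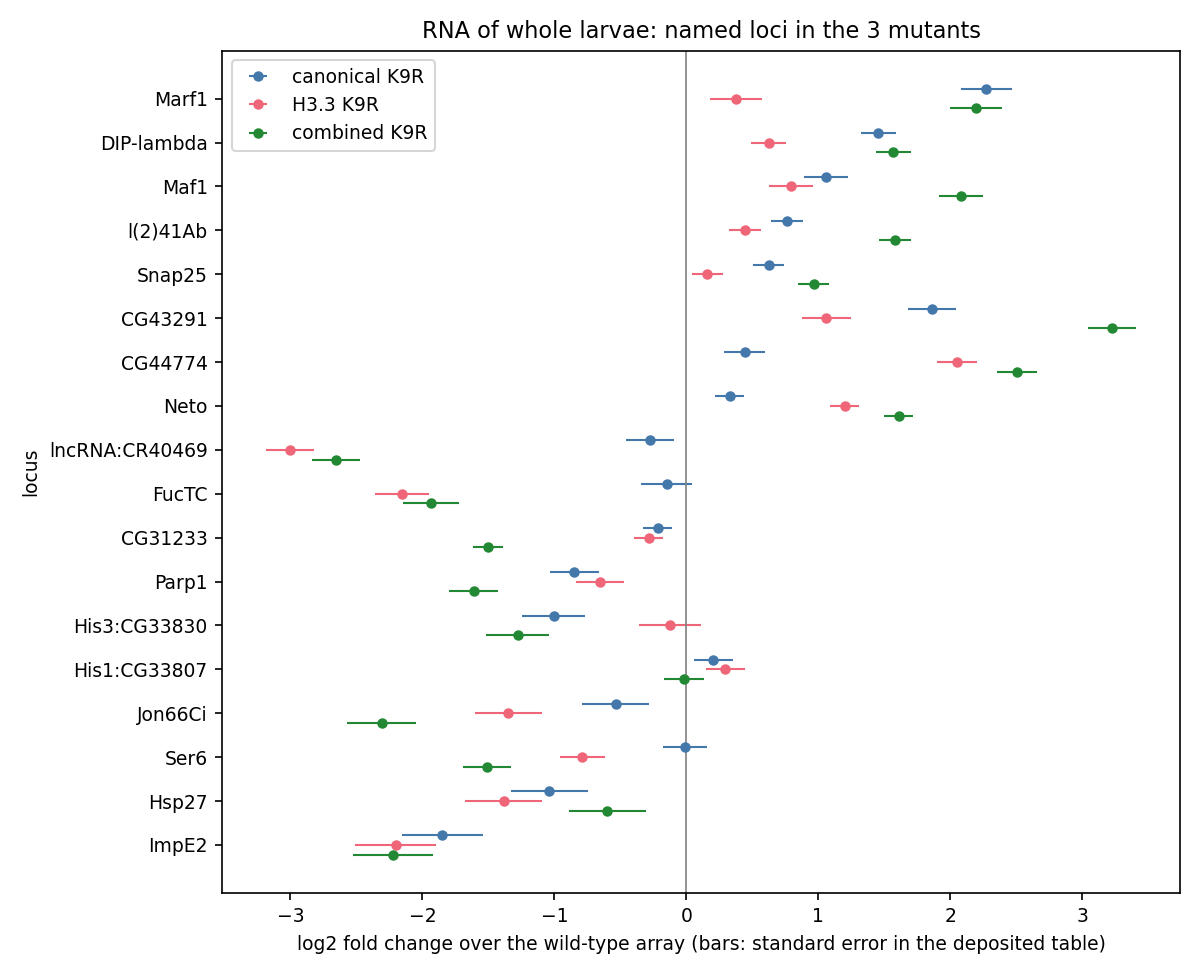
Log2 fold changes over the wild-type array control of named loci in the 3 K9R genotypes, points with bars of 1 standard error, both from the authors' deposited tables. Marf1 stood at 2.27 and 2.19 with the K9R array and 0.38 with H3.3 K9R alone, and CG44774 at 0.44, 2.05 and 2.5 in canonical, H3.3 and combined K9R.

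Digestive enzymes of the midgut fell in combined K9R (28 loci, median −0.75, adjusted p = 1.4e-12), with 0 higher, 18 lower and 19 lower adjusted over the list alone. Jon66Ci stood at −2.31 ± 0.26 (adjusted p = 8.8e-17), Ser6 at −1.51 ± 0.18, thetaTry at −1.43 ± 0.25 and Jon99Ciii at −1.19 ± 0.14 in the authors' deposited table. The canonical histone list had a median of −0.44 (adjusted p = 2.6e-09, with the same limit as above), 35 of 103 copies lower and 57 lower adjusted over the list alone, with 0 higher. They were all 15 His3 copies (median −1.20 in the authors' deposited table), 17 of 23 His2B, 2 of 20 His2A and 1 of 22 His4 loci. Ribosomal protein genes fell (62 loci, median −0.20, adjusted p = 3.5e-04), with 1 higher and 23 lower, and 2 and 27 adjusted over the list alone, RpL3 at −0.49 ± 0.12 and RpS5b at 1.18 ± 0.24 in the authors' deposited table. Replication genes fell (34 loci, median −0.44, adjusted p = 0.00887), 11 lower and 2 higher, and 14 and 2 adjusted over the list alone. RnrS, of nucleotide synthesis, stood at −1.36 ± 0.29, the helicase genes Mcm5 and dpa at −1.26 ± 0.30 and −0.88 ± 0.26, and the mitotic checkpoint gene BubR1 at 0.87 ± 0.26 in the authors' deposited table. Pericentromeric genes rose (24 loci, median 0.21, adjusted p = 0.00294), 10 higher and 3 lower, and 10 and 4 adjusted over the list alone, with CG41520 at 1.08 ± 0.13, Ir40a at 1.01 ± 0.14 and Snap25 at 0.96 ± 0.12 in the authors' deposited table. Neuronal genes rose (31 loci, median 0.23, adjusted p = 0.0186), 6 higher and 1 lower, also adjusted over the list alone, with the sodium channel gene para at 0.60 ± 0.15, fne at 0.50 ± 0.14 and the choline acetyltransferase gene ChAT at −0.53 ± 0.14 in the authors' deposited table. Oxidative stress genes fell (35 loci, median −0.29, adjusted p = 0.0489), 5 lower and 4 lower adjusted over the list alone, with GstE3 at −0.99 ± 0.25 and Trxr1 at −0.56 ± 0.14 in the authors' deposited table. With a preset correlation of 0.05 the adjusted p-values were 0.0750 for ribosomal, 0.159 for replication, 0.0672 for pericentromeric, 0.189 for neuronal and 0.293 for oxidative stress genes. On fold changes, those of ribosomal, pericentromeric and neuronal genes were 0.152, 0.141 and 0.121. On ranks that of pericentromeric genes was 0.0535, and among loci with a mean count of at least 10 that of oxidative stress genes 0.122. Heat shock genes, lower in both single changes, had an adjusted p of 0.429 here (median −0.27), with 3 lower and 2 lower adjusted over the list alone, Hsp110 at −0.88 ± 0.17 and Hsp27 at −0.60 ± 0.29 (adjusted p = 0.121) in the authors' deposited table.

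**Figure D3:**
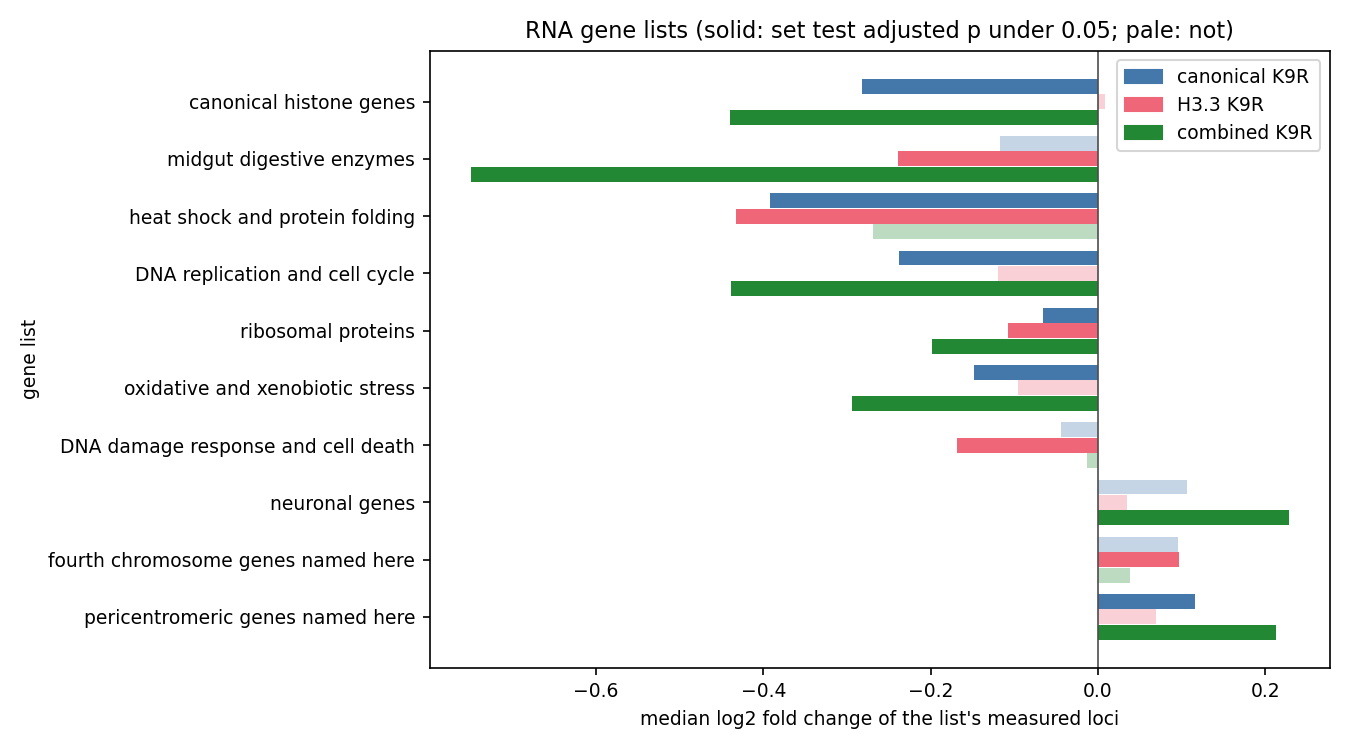
Median log2 fold change of the gene lists that passed the cameraPR test in at least 1 of the 3 K9R genotypes, computed from the authors' deposited tables. Solid bars passed the test and pale bars did not, and the lowest bar is that of midgut digestive enzymes in combined K9R, −0.75.

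The remaining lists did not pass the test as a whole in any genotype on the main statistic. Chromosome 4 and DNA damage genes, which passed in H3.3 K9R, are given here for the other genotypes, where they did not. On ranks, which were an alternative, muscle genes passed in canonical and H3.3 K9R (adjusted p = 0.0133 and 0.0228), Y genes and chromosome 4 genes in canonical K9R (0.0341 and 0.0269), cuticle genes in H3.3 K9R (0.0411) and hemocyte genes in combined K9R (0.0283). Factors of H3K9 methylation and heterochromatin (19 loci) had 0 higher and 2 lower in canonical K9R, 2 and 1 in H3.3 K9R and 3 and 3 in combined K9R, the same counts adjusted over the list alone (adjusted p = 0.155, 0.768 and 0.942). Among them wde, a cofactor of the methyltransferase Eggless, stood at −0.49 ± 0.14, 0.56 ± 0.14 and 0.51 ± 0.14 in canonical, H3.3 and combined K9R, and sov, a repressor in heterochromatin, at −0.03 ± 0.13 (adjusted p = 0.982), 0.38 ± 0.12 and 1.16 ± 0.12 (adjusted p = 1.6e-18), in the authors' deposited table. Ecdysone genes (30 loci) had 8 higher and 4 lower in combined K9R, and 9 and 4 adjusted over the list alone (adjusted p = 0.254), the nuclear receptor gene Hr4 at 0.73 ± 0.09 and ImpE1 at −0.67 ± 0.22 in the authors' deposited table. In canonical and H3.3 K9R ecdysone genes had 2 higher and 1 lower (2 and 2 adjusted over the list alone, adjusted p = 0.809) and 1 and 1 (also over the list alone, adjusted p = 0.547). Cuticle genes (88 loci) had 4 higher and 11 lower in combined K9R, and 4 and 9 adjusted over the list alone (adjusted p = 0.485), with the chitin-binding gene obst-A at −2.01 ± 0.26 and Cpr67B at 0.70 ± 0.12 in the authors' deposited table. In canonical K9R they had 1 higher and 0 adjusted over the list alone (adjusted p = 0.904), and in H3.3 K9R 2 lower, also adjusted over the list alone (adjusted p = 0.314). Germline genes (14 loci) had 0 called in canonical K9R, where 1 was higher adjusted over the list alone, 0 in H3.3 K9R, and 3 higher and 1 lower in combined K9R, also adjusted over the list alone (adjusted p = 0.942, 0.942 and 0.596). The germline helicase gene vas stood at −0.72 ± 0.14 and bru1 at 0.51 ± 0.15 in combined K9R in the authors' deposited table. Genes of the piRNA pathway (21 loci) had 0, 0 and 4 called, the last 1 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.813, 0.768 and 0.767). Y genes (6 loci) had ORY higher in canonical K9R, 1.08 ± 0.30 (adjusted p = 0.0129), and ORY higher and FDY lower in combined K9R, 1.73 ± 0.30 and −0.69 ± 0.20, in the authors' deposited table. The counts were the same adjusted over the list alone, and 0 in H3.3 K9R (adjusted p = 0.148, 0.708 and 0.643 for canonical, H3.3 and combined K9R). Genes of chromosome 4 had 0 called in canonical K9R (adjusted p = 0.366), and 2 higher and 4 lower in combined K9R, 1 and 3 adjusted over the list alone (adjusted p = 0.942), with Arf4 at −0.74 ± 0.18 and Syt7 at 0.53 ± 0.16 in the authors' deposited table.

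Fat body genes (23 loci) had 0 called in canonical K9R, 1 higher and 1 lower in H3.3 K9R, and 3 higher and 3 lower in combined K9R, the same adjusted over the list alone (adjusted p = 0.942, 0.776 and 0.942), with the lipase gene bmm at 0.82 ± 0.18 and Lsd-1 at −0.88 ± 0.23 in combined K9R in the authors' deposited table. Hemocyte genes (9 loci) had 0, 1 higher and 2 lower in the same order, also adjusted over the list alone (adjusted p = 0.596, 0.795 and 0.155). Muscle genes (23 loci) had 0, 0, and 2 higher and 1 lower, 0 adjusted over the list alone (adjusted p = 0.204, 0.181 and 0.776). DNA damage genes had 0 called in canonical K9R (adjusted p = 0.512), and 2 higher and 2 lower in combined K9R, also adjusted over the list alone (adjusted p = 0.809). Immune genes had DptB higher in canonical K9R, 1.22 ± 0.30, and 1 higher and 1 lower in combined K9R, 1 and 0 adjusted over the list alone, per the authors' deposited table (adjusted p = 0.930 and 0.768). Homeotic and Polycomb target genes (65 loci) had 0, 0 and 1 lower, 0 adjusted over the list alone (adjusted p = 0.294, 0.767 and 0.809). Wing disc patterning genes (42 loci) had 0, 0, and 1 higher and 3 lower, 0 and 1 adjusted over the list alone (adjusted p = 0.155, 0.294 and 0.942). Testis genes (37 loci), chosen with the Y genes as markers of sex, had 0 called in every genotype in the authors' deposited table. The count was the same adjusted over the list alone (adjusted p = 0.809, 0.930 and 0.942). Only 12, 9 and 9 of them had an adjusted p-value in canonical, H3.3 and combined K9R. The rest could not be called, so these counts cannot tell the sex of the larvae. Replacement and variant histones (4 loci) had only His3.3B called, in H3.3 K9R, also adjusted over the list alone (adjusted p = 0.942, 0.809 and 0.768). In lists of which members moved both ways, the median and the test differed in sign for heterochromatin factors in combined K9R, germline genes in H3.3 K9R, chromosome 4 genes in combined K9R, cuticle genes in canonical K9R and immune genes in canonical K9R. In H3.3 K9R the mean statistic of the immune genes was −0.07 and their median 0.04. The midgut (adjusted p = 0.199 in canonical K9R), replication (0.155 in H3.3 K9R), oxidative stress (0.421 in H3.3 K9R, with MtnA higher and GstD2 lower) and neuronal lists (0.268 and 0.485 in the single genotypes) did not pass elsewhere on the main statistic. Replication genes in H3.3 K9R passed on fold changes (adjusted p = 0.0467, and 0.0507 on ranks), and on ranks so did neuronal genes in canonical K9R (0.00806) and canonical histone genes in H3.3 K9R (0.00859), while midgut enzymes in canonical K9R had 0.0507. Where a list had 0 called by the authors' DESeq2 test, at most 4 of its members lay under an unadjusted p of 0.05, apart from the 6 DNA damage genes in H3.3 K9R.

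Setting the genotypes side by side asks whether variant and canonical K9R act on the same loci and whether their effects add. Of the 869 loci higher in combined K9R in the authors' deposited table, 223 were also higher in canonical K9R, 170 in H3.3 K9R, 95 in both and 571 in neither. Of the 1036 lower loci 35, 78, 5 and 928 were shared in this way per the authors' deposited table. Independent lists would share 27.8 and 23.1 of the higher and 5.43 and 17.1 of the lower loci. Canonical and H3.3 K9R shared 97 higher and 6 lower loci, against 6.49 and 0.660 for independent lists. The covariance of fold changes was 0.142 between canonical and combined K9R, 0.104 between H3.3 and combined K9R and 0.0548 between the single genotypes, against 0.0212, 0.0211 and 0.0210 in simulations of unchanged groups with a shared control. Correlations were 0.757, 0.611 and 0.508 in the same order, against 0.495, 0.495 and 0.497 simulated, and 74.7%, 66.6% and 65.4% of loci had the same sign, against 66.5%, 66.5% and 66.7%. What the shared control libraries add to the overlaps of calls was not measured. By the test of the difference, 159 of 10072 loci differed between combined and canonical K9R, 66 higher and 93 lower, and 344 between combined and H3.3 K9R, 178 higher and 166 lower. With the shared control removed from the error these were 661 and 1236. Relative to canonical K9R, combined K9R was higher by 2.06 ± 0.22 at CG44774 (adjusted p = 3.7e-17), 1.28 ± 0.15 at Neto, 1.19 ± 0.18 at sov (adjusted p = 1.8e-08), 1.06 ± 0.16 at CG42795 and 0.89 ± 0.13 at lncRNA:CR44999. It stood at −2.38 ± 0.26 at lncRNA:CR40469, −1.79 ± 0.28 at FucTC, −1.65 ± 0.26 at CG14219, −1.29 ± 0.16 at CG31233 and −1.10 ± 0.15 at MFS3. Relative to H3.3 K9R, it was higher by 2.94 ± 0.38 at lncRNA:CR42646, 2.16 ± 0.26 at CG43291 (adjusted p = 2.5e-13), 1.82 ± 0.28 at Marf1, 1.29 ± 0.23 at Maf1 and 1.14 ± 0.17 at l(2)41Ab. It stood at −2.0 ± 0.30 at CG14300, −1.57 ± 0.25 at CG41099, −1.33 ± 0.19 at BckdhB, −1.22 ± 0.16 at CG31233 and −1.18 ± 0.18 at CG8483. These differences are of values from the authors' deposited table. Pericentromeric loci made up 78 of the 178 loci higher than in H3.3 K9R (odds ratio 24.6, adjusted p = 1.4e-63), and 14 of the 66 higher than in canonical K9R (odds ratio 7.05, adjusted p = 4.0e-07).

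Canonical and H3.3 K9R differed at 120 loci, 95 higher in canonical K9R and 25 lower. Marf1 was higher in canonical K9R by 1.89 ± 0.28 (adjusted p = 5.2e-09), lncRNA:CR40469 by 2.73 ± 0.26 (adjusted p = 2.8e-23), FucTC by 2.01 ± 0.28, CR11023 by 2.63 ± 0.42 and CG34106 by 0.84 ± 0.14, as differences of values in the authors' deposited table. CG44774 stood at −1.61 ± 0.22, Btnd at −1.56 ± 0.28, wde at −1.05 ± 0.20 (adjusted p = 3.0e-05), Neto at −0.87 ± 0.15 and lncRNA:CR44999 at −0.66 ± 0.13 in the same difference of the authors' deposited table. Pericentromeric loci held 32 of the 95 (odds ratio 14.0, adjusted p = 1.1e-21) and scaffolds 14 (odds ratio 11.3, adjusted p = 1.3e-09). On the X arm and 2L, 1.09% of loci differed in this test (36 of 3313), against 0.559% on 2R, 3L and 3R (34 of 6080). Combined K9R departed from the sum of the single effects at 15 loci, 2 above and 13 below, or 73 with the shared control removed. CG31233 lay below the sum by −1.0 ± 0.19 (adjusted p = 7.7e-04), CG14300 by −1.81 ± 0.36 (adjusted p = 0.00135), asRNA:CR45343 by −1.57 ± 0.37, BckdhB by −0.97 ± 0.23 and CG8483 by −0.90 ± 0.22, computed from the authors' deposited table. The 2 loci above the sum, on 3R and the X, had no gene name. Of the 13 below it, 5 were pericentromeric (odds ratio 16.0, adjusted p = 2.1e-04) and 4 on scaffolds (odds ratio 27.5, adjusted p = 1.3e-04).

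Wing discs of the H3.3A null differed from wild type in both directions, with many lower regions near the centromeres, and effects of the stock were not separated from those of the mutation. Of 19733 tested FAIRE regions, the authors' deposited table called 1736 in the H3.3A null (8.80%), 946 higher and 790 lower. A region in nAChRalpha3, an acetylcholine receptor subunit (X, 8294268 to 8296239), rose by 5.97 ± 0.17, a region in lncRNA:flam, a piRNA cluster (X, 21711449 to 21714438), by 4.17 ± 0.11, and a region at lovit (3L, 25287238 to 25291580) by 3.36 ± 0.09 in the authors' deposited table. A region 5158 bp from robo3 (2L, 1301755 to 1302313) stood at −4.04 ± 0.20, and 2 regions near TpnC41C (2R, 5049137 to 5051810 and 5055148 to 5056726) at −3.68 ± 0.12 and −3.37 ± 0.11 in the authors' deposited table. Of 1362 pericentromeric regions 19.2% were lower (262, odds ratio 8.05, adjusted p = 4.8e-112) and 111 higher (odds ratio 1.86). Neighbouring regions often changed together, so p-values by location or arm here and below overstate the evidence. With boundaries 1 Mb towards the centromere 125 of 972 were lower (odds ratio 4.01), and into the arms the ratio was 5.27. On chromosome 4, 11 of 100 regions were higher (odds ratio 2.47, adjusted p = 0.0112) and 10 lower (odds ratio 2.68, adjusted p = 0.00932), neither past the test with an absolute log2 fold change of 1 or more (adjusted p = 0.0731 and 0.386). Of 1402 scaffold regions 328 were higher and 160 lower. Of 85 on the Y 18 were higher (odds ratio 5.42, adjusted p = 1.5e-07) and 5 lower (adjusted p = 0.426). By arm, 9.99% of X regions (341 of 3414) and 4.69% of 2L regions (137 of 2924) were called, against 3.25%, 3.48% and 3.41% on 2R, 3L and 3R. The X share was higher than that of 2R, 3L and 3R (odds ratio 3.17, adjusted p = 1.2e-45), as was that of 2L (odds ratio 1.40, adjusted p = 0.00286). Over 2R, 3L and 3R alone, 3.38% of regions were called.

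H3.3B-K9R with H3.3A present gave 1288 called regions in the authors' deposited table (6.53%), 779 higher and 509 lower. The nAChRalpha3 region rose by 6.33 ± 0.17 and a region near CG9380 at the tip of 2R (25268594 to 25272227) by 3.96 ± 0.12, while the flam region stood at 0.26 ± 0.12 without a call, in the authors' deposited table. A region at Msp300 and Cyp28d2 (2L, 5206760 to 5209763) decreased by 2.09 ± 0.09, one at CG9799 (3R, 13387007 to 13388257) by 1.79 ± 0.13, and one at Pka-R1 (3L, 20823152 to 20823532) by 1.54 ± 0.10 in the authors' deposited table. The X arm held the largest number of arm calls, 12.4% of its regions (422 of 3414, odds ratio 5.25 against 2R, 3L and 3R, adjusted p = 7.6e-95). It includes the block at flam, with 28 of 61 regions higher, and the X tip, with 26 of 51 higher and 6 lower. The split by arm was not repeated with moved boundaries. On 2L, although this genotype keeps H3.3A, 5.16% were called (151 of 2924, odds ratio 2.03, adjusted p = 2.0e-10), and over 2R, 3L and 3R alone 2.62%. Pericentromeric regions were enriched among the lower ones (79 of 1362, odds ratio 2.57) and less frequent among the higher ones (38, odds ratio 0.683, adjusted p = 0.0254). That ratio became 3.67 with boundaries moved 1 Mb into the arms. The enrichment of lower ones did not pass with boundaries 1 Mb towards the centromere (31 of 972, odds ratio 1.26, adjusted p = 0.266) or with an absolute log2 fold change of 1 or more (odds ratio 1.47, adjusted p = 0.371). On chromosome 4, 9 regions were higher (odds ratio 2.42, adjusted p = 0.0217) and 9 lower (odds ratio 3.78, adjusted p = 0.00167), without passing under that requirement on the fold change (adjusted p = 0.185 and 1). Of scaffold regions 162 were higher and 140 lower. Of 85 on the Y 4 were higher (odds ratio 1.20, adjusted p = 0.610) and 1 lower.

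The double mutant, with no H3.3A and K9R in H3.3B, had 1562 called regions over wild type in the authors' deposited table (7.92%), 929 higher and 633 lower. On chromosome 4, 26 of 100 regions were lower (odds ratio 11.0, adjusted p = 1.3e-16) and 1 higher, and 18 of the 26 lay among 27 regions at the end of the chromosome. Cadps, a regulator of dense-core vesicles, was the nearest gene to 2 of them, 21170 and 40350 bp away. The one at 1292931 to 1293988 of chromosome 4 stood at −1.79 ± 0.11, and the one at 1312113 to 1313338 at −1.73 in the authors' deposited table. There both were higher in the H3.3A null, 0.27 ± 0.09 and 0.40. A region near lncRNA:CR40469 (X, 86448 to 87778) decreased by 1.76 ± 0.11, the nAChRalpha3 region rose by 5.89 ± 0.17 and the flam region by 2.73 ± 0.11 in the authors' deposited table. Of the regions low in the H3.3A null, the robo3 one stood at −0.36 (adjusted p = 0.0597) and the first TpnC41C one at −0.27 (adjusted p = 0.0522), without a call, in the authors' deposited table. The second TpnC41C region was called there at −0.42 ± 0.08 in the authors' deposited table. Of the pericentromeric regions 104 were higher (odds ratio 1.76) and 65 lower (odds ratio 1.57, adjusted p = 0.00194). Counting calls with an absolute log2 fold change of 1 or more, the ratio for lower regions turned to 0.216. It did not pass with boundaries 1 Mb into the arms (1.13, adjusted p = 0.342) or towards the centromere (1.17, adjusted p = 0.413), and the ratio for higher regions was 4.16 with boundaries into the arms. Of 1402 scaffold regions 251 were higher (odds ratio 5.68) and 199 lower (odds ratio 6.82). Of 85 on the Y 15 were higher (odds ratio 4.39, adjusted p = 1.5e-05) and 2 lower. By arm, 13.5% of X regions were called (462 of 3414, odds ratio 5.10, adjusted p = 1.1e-100), 4.31% of 2L regions (odds ratio 1.47, adjusted p = 0.00129), and 2.98% over 2R, 3L and 3R alone.

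The double mutant and the H3.3A null differ in K9R of H3.3B, their only H3.3, stocks aside. The authors' deposited table called 1282 regions (6.5%), 732 higher and 550 lower. The robo3 region rose by 3.69 ± 0.20, the TpnC41C region by 3.41 ± 0.12 and a region near CG14621 (X, 22412085 to 22412905) by 3.45 ± 0.18 in the authors' deposited table. Regions near Cadps on chromosome 4 stood at −2.06 ± 0.10 and −2.14 ± 0.11, one near lncRNA:CR40469 at −2.13 ± 0.11 and the flam region at −1.44 ± 0.08 in the authors' deposited table. Chromosome 4 had 25 of 100 regions lower (odds ratio 12.2, adjusted p = 4.9e-17), 19 of them among the 27 at its end. Of the pericentromeric regions, 15.6% were higher (212 of 1362, odds ratio 6.33, adjusted p = 2.4e-77), with an odds ratio of 2.76 for boundaries 1 Mb towards the centromere. Lower pericentromeric regions were 62 (odds ratio 1.76, adjusted p = 1.6e-04), without passing with boundaries into the arms (adjusted p = 0.257) or towards the centromere (adjusted p = 0.591). Of 1402 scaffold regions 270 were lower (odds ratio 15.6, adjusted p = 3.3e-165) and 229 higher (odds ratio 6.92). On the Y 7 of 85 were lower (odds ratio 3.18, adjusted p = 0.0119) and 5 higher (adjusted p = 0.276). With an absolute log2 fold change of 1 or more 1 was lower (adjusted p = 0.470). By arm, 10.3% of X regions were called (351 of 3414) against 1.03% on 2R, 3L and 3R (107 of 10438, odds ratio 11.1, adjusted p = 4.0e-124), and 0.308% on 2L (9 of 2924, odds ratio 0.298, adjusted p = 1.8e-04), the arm of the H3.3A mutation that both genotypes carry.

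**Figure D4:**
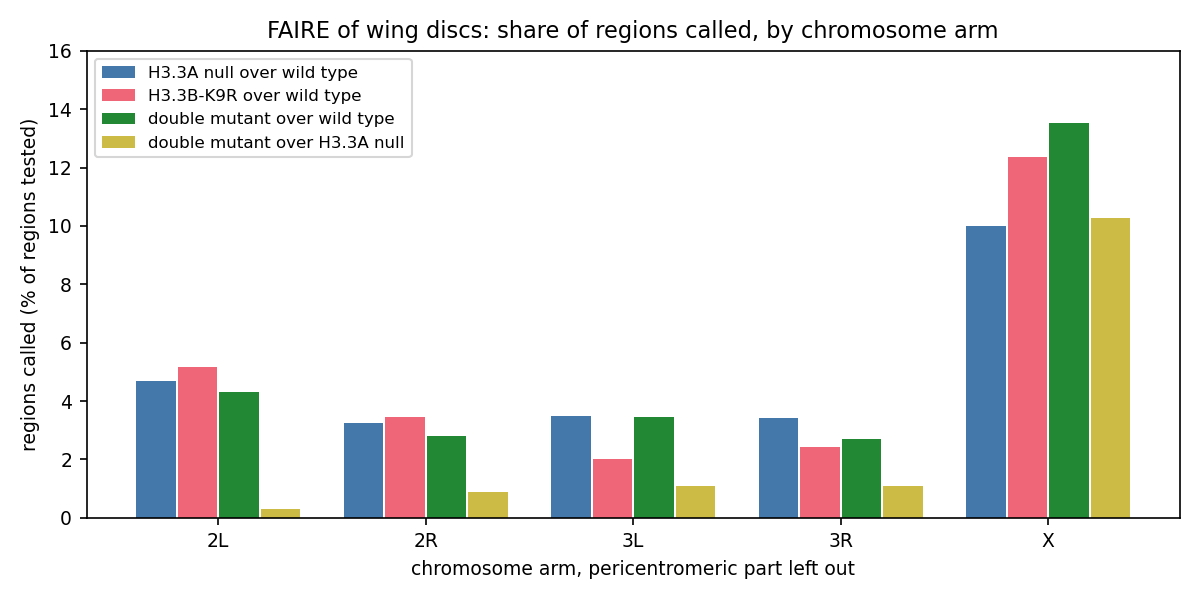
Percent of FAIRE regions called on each chromosome arm in the 4 comparisons, from the authors' deposited adjusted p-values under 0.05. The X held the highest share in each, 9.99%, 12.4%, 13.5% and 10.3%, and 2L the lowest in the double mutant over the H3.3A null, 0.308%.

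The effect of H3.3B-K9R without H3.3A differed from that with H3.3A at 957 regions, 491 higher and 466 lower, by a test of the difference between comparisons that share no library. The nAChRalpha3 region differed by −6.40 ± 0.19 and the region near CG9380 by −4.04 ± 0.15, and the robo3 and TpnC41C regions by 5.01 ± 0.24 and 4.63 ± 0.16, computed from the authors' deposited table. On chromosome 4, 20 regions had a lower effect without H3.3A (odds ratio 10.8, adjusted p = 6.8e-13), and pericentromeric regions were enriched among the higher ones (181, odds ratio 8.93, adjusted p = 3.6e-84). By arm, 192 of 3414 X regions (odds ratio 3.85, adjusted p = 2.0e-33) and 106 of 2924 on 2L (odds ratio 2.43, adjusted p = 8.4e-11) differed. Over 2R, 3L and 3R alone 1.52% of regions differed, against 4.85% in the genome. H3.3A null and double mutant shared 512 higher and 308 lower regions (44.5 and 25.3 for independent lists), H3.3B-K9R and double mutant 591 and 309 (36.7 and 16.3), and H3.3A null and H3.3B-K9R 357 and 229 (37.4 and 20.4). What the shared wild-type libraries add to these overlaps was not measured. H3.3B-K9R over wild type and double mutant over H3.3A null, which share none, had 309 higher and 149 lower regions in common (28.9 and 14.2 for independent lists), with a covariance of 0.0158 against 5.9e-06 simulated. Covariances of the 3 comparisons with wild type were 0.0862, 0.0836 and 0.0678 in the order above, each against 0.0137 or 0.0138 simulated.

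Regions overlapping or nearest to loci that pattern the wing disc were called less often than all other regions, a contrast that shrank on the arms. Of 456 such regions 2 were higher and 2 lower in the H3.3A null (0.439% each, against 4.90% and 4.09% elsewhere, adjusted p = 4.2e-07 and 9.0e-06), and 2 and 1 in H3.3B-K9R (adjusted p = 1.2e-05 and 3.0e-04). In the double mutant 2 were higher and 2 lower (adjusted p = 5.1e-07 and 1.7e-04), and over the H3.3A null 0 were higher and 1 lower by the authors' DESeq2 test (adjusted p = 2.9e-07 and 1.7e-04, Fisher exact test). Against other regions of 2R, 3L and 3R, chosen after seeing the data, 4 of 328 were called in the H3.3A null (odds ratio 0.345, Fisher exact test, p = 0.0278). In H3.3B-K9R these were 3 (odds ratio 0.336, Fisher exact test, p = 0.0509), in the double mutant 4 (0.394, p = 0.0665) and over the H3.3A null 1 (0.289, p = 0.266). Regions assigned to the chromosome 4 genes of the list, 81 in all, had 25 lower in the double mutant (30.9%, odds ratio 14.0, adjusted p = 3.3e-17). Over the H3.3A null 24 were lower (29.6%, odds ratio 15.3, adjusted p = 3.3e-17). In the H3.3A null 10 were higher and 8 lower, and in H3.3B-K9R 9 and 9. The block at the end of the chromosome, given below, held 18 and 19 lower regions in the first 2 comparisons. All these list counts largely repeat that block. Regions at the pericentromeric genes, 179 in all, had 17 higher and 28 lower in the H3.3A null (odds ratios 2.1 and 4.57, adjusted p = 0.0114 and 5.0e-09), 6 and 8 in H3.3B-K9R, 16 and 9 in the double mutant, and 14 and 4 over the H3.3A null. Blocks of neighbouring regions were also chosen after their values were seen. Regions in most of them changed together, which the Fisher tests above ignore. How FAIRE reads with several positions were counted is not given, so alike blocks may share reads. At flam (X, 21662562 to 21788760) 30 of 61 regions were higher and 1 lower in the H3.3A null, 28 and 0 in H3.3B-K9R, 37 and 0 in the double mutant, and 16 and 3 over the H3.3A null in the authors' deposited table. At the tip of the X (187 to 99171) 35 of 51 regions were higher and 4 lower in the H3.3A null, 26 and 6 in H3.3B-K9R, 17 and 19 in the double mutant, and 0 and 41 over the H3.3A null in the authors' deposited table. Beside TpnC41C (2R, 5049137 to 5088863) 8 of 9 regions were lower in each single mutant and 1 in the double mutant, and 8 were higher over the H3.3A null, per the authors' deposited table. At the end of chromosome 4 (1268614 to 1344079) 10 of 27 were higher and 7 lower in the H3.3A null, 9 and 7 in H3.3B-K9R, 1 and 18 in the double mutant, and 0 and 19 over the H3.3A null, per the authors' deposited table. At the tip of 2R (25206321 to 25286297) these were 11 and 4, 8 and 5, 8 and 6, and 1 and 5 of 21 in the authors' deposited table.

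Open chromatin and RNA were set side by side over loci that a FAIRE region overlaps, although tissue, stage and canonical histone genes differ. RNA in H3.3 K9R averaged 0.14 at 151 loci with a region higher in the double mutant, 0.03 at 182 loci with a lower region and −0.03 at 4762 loci with uncalled regions, as log2 fold changes from the authors' deposited table. Loci with higher regions exceeded those with lower regions by 0.11 (95% bootstrap interval 0.03 to 0.19, two-sided permutation test across loci, p = 0.00678, adjusted p = 0.00678), and uncalled loci by 0.17 (adjusted p = 3e-05). Loci with lower regions exceeded uncalled loci by 0.07 (adjusted p = 2.7e-04). The raw p of the comparison of higher regions with uncalled ones, 1e-05, is the smallest that these permutations give. Loci are not independent replicates, and the X holds a larger share of the called regions and loci than 2R, 3L and 3R. The test pooled loci of the arms, the pericentromeres and chromosome 4 without matching them by location.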

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

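The tests of the share of 2L, of the sex of the discs and of RNA by arm were chosen only after the result was seen.

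The effect of H3.3B-K9R on open chromatin differed with and without H3.3A at 957 regions by the test of the difference, 20 of them on chromosome 4 with a lower effect without H3.3A. Among the regions with the lowest statistics, the effect without H3.3A minus that with H3.3A was −6.40 at nAChRalpha3, −4.83 on the unplaced scaffold region from 614 to 3176, −4.54 and −4.47 at the tip of the X (76844 to 79201 and 55762 to 57526) and −4.04 near CG9380 at the tip of 2R. Among those with the highest, it was 5.01 near robo3, 4.63, 3.95 and 3.75 beside TpnC41C, and 2.16 at Msp300 and Cyp28d2. In the first group each single mutant was raised over wild type and the double mutant was not raised further, and near robo3 and TpnC41C the single mutants were lowered and the double mutant was less so, in the authors' deposited table. At Msp300 and Cyp28d2 the double mutant, −0.84, stood close to the H3.3A null, −0.91, and H3.3B-K9R lower, −2.09, in the authors' deposited table. Such departures from a sum are measured on the log2 scale. The differences were more frequent on the X (192 of 3414, odds ratio 3.85) and 2L (106 of 2924, odds ratio 2.43). At nAChRalpha3 all 3 mutants lay near one another and apart from wild type, at 5.97, 6.33 and 5.89 in the authors' deposited table. Stock differences were not separated from effects of the mutations.

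In RNA, combined K9R departed from the sum of both single effects at 15 loci by the same test. The named ones were CG31233, −1.0, CG14300, −1.81, asRNA:CR45343, −1.57, BckdhB, −0.97, and CG8483, −0.90, all below it.

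Between the double mutant and the H3.3A null, 10.3% of the X regions were called, 1.03% of those on 2R, 3L and 3R, and 0.308% of those on 2L. The X regions include the block at flam, with 16 of 61 higher and 3 lower, and the X tip, with 41 of 51 lower. The split by arm was not repeated with moved boundaries. A different share of male and female discs is argued against by the median of the X regions, which departed from that of the autosomal arms by −0.00174 (95% bootstrap interval −0.00863 to 0.00481). Differences between fly stocks that follow 2L, which both genotypes carry from the H3.3A null, may account for the low share there, but the odds ratio of 0.298 (9 of 2924 against 107 of 10438, Fisher exact test, p = 6.5e-05) restates that share and leaves this open, while H3.3B-K9R, which keeps H3.3A, had an excess on 2L over wild type (151 of 2924, odds ratio 2.03). On the X, calls were fewer between the double mutant and H3.3B-K9R, which share an X, with 32 of 3414 (0.937%) and an odds ratio of 2.01 (Fisher exact test, p = 0.00282), or 78 of 3414 and 1.46 with the shared wild type removed from the error, against 351 of 3414 and 11.1 between the double mutant and the H3.3A null. A ratio of 1 or more was first set to exclude a shared X, but after the values were seen that bound was judged wrong, since calls that remain on the X exclude nothing about those lost, and the H3.3A null, without a mutation in H3.3B, also had an excess on the X over wild type (341 of 3414, odds ratio 3.17), so the mutation in H3.3B and other sequence of the stocks cannot be told apart.

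RNA loci that differed between canonical and H3.3 K9R were also more frequent on the X and 2L. The shares were 1.09% on the X and 2L and 0.559% on 2R, 3L and 3R. Stock differences that follow the X and 2L could give such an excess, but its odds ratio of 1.95 (36 of 3313 against 34 of 6080, Fisher exact test, p = 0.00558) comes from the libraries in which it was first seen and leaves them open, and the histone array on 2L held 0 of these loci. The H3.3 mutations lie on the same arms, so effects on linked genes stay open as well, untested. lncRNA:CR40469, CG44774 and Neto on the X and CR11023 on 2L are among the loci concerned.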

How the results depend on the processing

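The counts over 2R, 3L and 3R alone, and those without the reference histone array of 2L, were chosen only after the result was seen. With an absolute log2 fold change of 1 or more besides the adjusted p-value, RNA calls were 162, 130 and 456 in canonical, H3.3 and combined K9R, and FAIRE calls 494 in the H3.3A null, 342 in H3.3B-K9R, 447 in the double mutant and 315 for the double mutant over the H3.3A null. The loss follows from the added requirement. An adjusted p under 0.01 left 1226 RNA calls in combined K9R, and the total counts of the other comparisons stayed within 1.5 times, while lower calls went from 41 to 22 in canonical K9R and from 126 to 74 in H3.3 K9R. Adjustment over every p-value, or a mean count of at least 10, left every total count of calls within 1.5 times. With the shared control removed, which makes the error smaller, 661 loci differed between combined and canonical K9R, 1236 between combined and H3.3 K9R, and 73 from the sum.

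Over 2R, 3L and 3R alone, the share called was 1.05% instead of 3.55% in canonical K9R, 2.51% instead of 4.31% in H3.3 K9R, and 21.9% instead of 25.0% in combined K9R. In FAIRE it was 3.38% in the H3.3A null, 2.62% in H3.3B-K9R, 2.98% in the double mutant, 1.03% for the double mutant over the H3.3A null and 1.52% for the difference in effect. Wing disc loci had odds ratios of 0.345 in the H3.3A null, and of 0.336, 0.394 and 0.289, no longer past the test, in H3.3B-K9R, the double mutant and the double mutant over the H3.3A null. Without the histone array the odds ratio of 2L went from 1.88 to 0.93 in canonical K9R. Leaving out the array also changed the ratio of lower pericentromeric loci in canonical K9R with boundaries 1 Mb into the arms from 17.5 to 8.05, since that move makes the array pericentromeric. That of higher ones in combined K9R went from 3.2 to 4.06. The arms 2R, 3L and 3R leave out the pericentromeres, Y, scaffolds, chromosome 4, 2L and X, where the shares were mostly higher.

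With a preset correlation of 0.05, which lowers the power of the list test, 3 lists were called in canonical K9R instead of 6, 2 in H3.3 K9R instead of 5 and 2 in combined K9R instead of 7. On ranks 8 were called in H3.3 K9R, and on fold changes 4 in combined K9R, for which the cause was not tested. Calls of heat shock genes in canonical and H3.3 K9R and midgut enzymes in H3.3 and combined K9R held under the 4 alternatives of the list test. No alternative counted the near-identical histone copies, or the near-identical Hsp70 copies of the heat shock list, as one gene. Of single list results, 61 of 72 kept direction and side of the threshold with the larger preset, 62 of 72 on ranks, 65 of 72 on fold changes and 67 of 69 with a mean count of at least 10.

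The odds ratio of higher pericentromeric FAIRE regions in H3.3B-K9R turned from 0.683 to 3.67 with boundaries 1 Mb into the arms and was 0.876, without passing the test, with boundaries 1 Mb towards the centromere. That of lower pericentromeric regions in the double mutant turned from 1.57 to 0.216 with the fold requirement. The cause was not tested. Of 24 location results in FAIRE, 24 kept direction and side of the threshold with a mean count of at least 10, 20 with the fold requirement, 21 with boundaries moved into the arms and 20 towards the centromere. Of 18 in RNA these were 18, 17, 18 and 17. Overlaps at an adjusted p under 0.01 stayed within 1.5 times in 8 of 8 cases in FAIRE and 3 of 6 in RNA.

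Leaving out each replicate, a replicate block, a refit with DESeq2 and counts of other groupings of the libraries were not run, because they need values per library. No paired analysis was possible because the tables used hold no values of single libraries. FAIRE against RNA by distance to transcription starts, with its 2 alternatives (a distance within 5 kb, and an absolute log2 fold change of 1 or more in FAIRE), was not run for lack of strand. The low fold changes at few counts limit what can be said of loci with a mean count under 10, 2727 in RNA and 4 in FAIRE.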

Other observations

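The test of repeated sequence was chosen only after the result was seen, and its rule was then changed again, first from loci of any length to short loci and later by a minimum number of called loci, each time after values were known.

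Single members of lists that did not pass the test also changed in combined K9R. In metabolism and growth, the insulin receptor gene InR rose by 0.60 ± 0.15 and the sterol transporter gene Npc1a by 0.56 ± 0.16, and Gpdh1 stood at −0.51 ± 0.17 in the authors' deposited table. Among muscle genes, sls and up stood at 0.32 ± 0.13 and 0.30 ± 0.12, and the calcium pump gene SERCA at −0.46 ± 0.15 in the authors' deposited table. Of the hemocyte list, Col4a1 stood at −0.36 ± 0.13 and Ppn at −0.30 ± 0.10, while vkg (adjusted p = 0.122) and Pxn (adjusted p = 0.188) were not called, in the authors' deposited table. Among signalling genes of the discs, Ser stood at −0.63 ± 0.15, ptc at −0.40 ± 0.15 and EcR at 0.39 ± 0.14 in the authors' deposited table. The antimicrobial peptide gene Dro rose by 1.25 ± 0.24, the checkpoint kinase gene lok fell by 0.74 ± 0.18, and the repair genes Xpc and mre11 rose by 0.45 ± 0.12 and 0.53 ± 0.20 in the authors' deposited table.

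RNA from the Y and from scaffolds was higher in all 3 K9R genotypes. A larger share of male larvae would raise the male RNA roX2 with the Y loci, but roX2 lay below the median of 45 Y loci by −3.75 of its standard errors in canonical K9R, −2.63 in H3.3 K9R and −3.12 in combined K9R, with a mean count of 470, which argues against it as the whole cause. Repeated sequence whose reads were assigned to scaffolds and the Y could also raise them, and then short pericentromeric genes, with little room for repeats, should not rise. In canonical K9R, named pericentromeric loci of 5 kb or less were higher more often than arm loci of that length, with an odds ratio of 16.5 (2 of 73 against 7 of 4110, Fisher exact test, p = 0.00999), and at any length with 12.8 (13 of 159 against 50 of 7236, p = 5.3e-10). The ratio at any length decides nothing, since long loci have room for repeats, and only 2 short loci were higher, fewer than the 5 required after this was seen, so repeats stay open beside a release of silencing by K9R, which was not tested separately.

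A hypothesis stated before its result was seen, with overlap in place of the planned distance to transcription starts, was that a region more open in discs of the double mutant lies in a locus with more RNA in H3.3 K9R larvae. Loci with higher regions exceeded loci with lower regions by 0.11 on the log2 scale (95% bootstrap interval 0.03 to 0.19, permutation p = 0.00678), consistent with it. Loci with lower regions also exceeded loci with uncalled regions, by 0.07 (adjusted p = 2.7e-04), and those with higher regions did by 0.17 (adjusted p = 3e-05), so the direction of the FAIRE change did not order the 3 groups. Tissue, stage and histone genes differ between the assays, and shared stock differences on the X and 2L may contribute. Pericentromeric loci were higher more often than arm loci in H3.3 K9R RNA, 27 of 345 against 97 of 7019. Loci were not matched by location, so their location may contribute too.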
